A study of Homo sapiens with 104 samples.

How the data were processed

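Biotin-labelled cRNA from untreated and MNNG-treated cells of 26 lymphoblastoid lines was hybridised to Affymetrix arrays with 54675 probe sets, in duplicate for each line and condition (104 arrays). The deposited values are PLIER intensities on a linear scale, per the submitters' processing notes. The version of PLIER, the probe model and any array batches are not given in the sources used here. The values have a floor of 16 and reach 65535, which 71 values do. Median intensity per array was 16.0 to 64.4, so many probe sets lie near the floor, where differences cannot be measured. No values of a second assay were used.

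Intensities were transformed as log2 of the value plus 16. The array medians then differed by 1.33, more than the 0.2 set beforehand, so arrays were quantile normalised with limma. Probe sets were named with the annotation of the platform, in which 41097 had a single gene symbol, 1801 had several and 11777 had none, and the last 2 kinds were left out. The probe set with the highest mean stood for each of 19775 genes, and the 30% of genes with the lowest mean were left out, which left 13842 genes. No genome or coordinates were used. Tools were R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for the figures.

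All adjusted p-values of genes come from limma (linear models with a moderated test, prior spread following mean level) with Benjamini-Hochberg adjustment, and genes were called at an adjusted p below 0.05. Counts are also given for a fold of at least 1.5. For the panel, duplicate arrays were averaged and the line was a block, so that the line was the independent unit. Differences in response between lines, and differences between untreated lines, were tested with limma's F test on single arrays. Responses of single lines, of TK6 and of MT1, their difference, and untreated MT1 minus TK6 were contrasts in 1 model with a mean for each of the 52 groups. Standard errors are those of the moderated test. Named genes were chosen by a rule set before the data were examined: the 10 largest rises and falls in the panel among called genes that moved the same way in at least 20 of 24 lines, the 6 largest each way for TK6 and MT1 where all arrays of the groups lay apart, the 10 with the largest F, up to 4 called genes of each list with the largest change, and a fixed set of repair and damage genes. With 19 lines the rule asked for 16. From these, those named in the text were picked. Some genes are not reported here. Genes whose level depends on the sex of the donor were not named.

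A set of 28 lists with 735 entries, 658 of them matched to a probe set, was written before the data were examined. They were damage targets, damage checkpoint, apoptosis, base excision and direct reversal, mismatch, nucleotide excision and homologous recombination repair, G1/S, G2 and mitosis, histones, immediate early, NF-kB, interferon, HLA class II, the amino acid, unfolded protein, oxidative stress and heat shock responses, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins and ribosome biogenesis. Markers of B cells, plasma cells, T and NK cells, myeloid cells, and fibroblasts and epithelia made up the other lists. Lists were tested with limma's camera at its preset correlation between genes, and beside it with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction. Untreated levels of repair genes were related to each line's mean change of the damage-target list by Pearson and Spearman correlation with 100000 permutations, two-sided, adjusted over 6 relations. The family was planned with 10 relations, and 4 are not analysed here.

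After the data were seen, 22 MNNG arrays were set aside where a pair of probe sets for the spiked-in cre transcript differed by more than 2 log2 units in the direction never seen in the other arrays, and every comparison and alternative was repeated on 82 arrays. Groups left with 1 array were assumed to vary like the others. Alternatives were pseudocounts of 1, 64 and, added later, 0, values as deposited, centring on array medians, no filter and a 50% filter, the mean of all probe sets of a gene, no trend, array weights, no line block, a replicate block, a fit of the TK6 and MT1 arrays alone, a background covariate, added later, and leaving out each replicate or line.

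The analysis was tested on simulated data with 13842 genes, 200 of them changed. All simulations used the layout of the 82 arrays and the spread measured in them. The rates below therefore do not apply to the counts from all arrays. The panel test recovered 70%, 99.5% and 100% of changes of 0.2, 0.5 and 1 log2 unit, with 10, 13 and 15 false calls. The TK6 test recovered 34.5%, 90% and 99.5% of changes of 0.5, 1 and 2, and the test of TK6 minus MT1 recovered 7%, 59.5% and 93%. The F tests recovered 31%, 89.5% and 99% for response differences and 77.5%, 98.5% and 100% for untreated lines. In MT1, where nothing was changed, 0 genes were called. The changed list was called with 1 other of the 28, and a relation made with MGMT (r = -0.987) was found with 1 other past the threshold. In the group and list simulations every group had the same spread, and genes varied independently. These simulations could therefore not check whether a group with 1 array varied like the others, or the preset correlation of camera.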

Results

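Transcript levels were measured with oligonucleotide arrays in 26 human lymphoblastoid (B-cell derived) cell lines: a panel of 24 numbered lines, the established line TK6, and MT1, a derivative of TK6 selected for resistance to alkylating agents and deficient in mismatch repair. Each line was grown to mid log phase and examined untreated and after MNNG, a methylating agent whose most toxic product is a methylated guanine that the protein MGMT repairs by direct reversal. TK6 and MT1 both lack MGMT. Every line and condition had duplicate arrays, which gave 52 untreated and 52 treated arrays in 52 groups of 2. The series was set up to examine expression differences between the lines and their killing by MNNG. The dose, the exposure time and the killing of each line are not given in the sources used here, so no comparison uses them. The number of arrays limits the precision, and since nothing says that duplicates came from separate cultures, p-values that rest on duplicates may measure technical spread alone.

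Of the 52 MNNG arrays, 22 stood apart from all other arrays, and 0 of the 52 untreated arrays did. In these 22, a pair of probe sets for the same spiked-in phage transcript, cre, differed by -5.19 to -6.45 log2 units (mean -5.74, SD 0.38), against 0.082 to 0.83 (mean 0.43, SD 0.14) in the other 82. Their median correlation with untreated arrays was 0.553 to 0.664, against 0.896 to 0.963 for the other arrays. Of 3315 bright probe sets, 40.8% to 58.1% (median 51.2%) had lost over 2 log2 units in each of the 22, against 0% to 3.23% in the other MNNG arrays. The 22 comprised 21 of the panel's MNNG arrays and 1 of the MT1 MNNG arrays. In the panel, 5 lines had both MNNG arrays among them, 11 lines had 1, and 8 lines had none, so 19 lines kept at least 1 MNNG array. Each comparison of genes below therefore gives the count from all arrays, as planned before the data were examined, and the count from the 82 arrays. Counts of called lists below come from the 82 arrays. With all arrays, camera at its preset correlation called 10 lists in the panel, 11 in TK6, 10 in MT1 and 9 for TK6 minus MT1. Setting the 22 arrays aside was chosen after seeing the data. Values of genes and gene lists come from the 82 arrays and are log2 changes, with the standard error after ±. The scale ends at a level of 5, so a rise from a level near it or a fall to one is a lower bound of the change, and its standard error does not cover this limit. Since the 22 are all MNNG arrays, they hold samples of 1 treatment only and give no comparison of treated with untreated within themselves. Among the 82 arrays, each array correlated best with another array of its own line, and the 35 duplicate pairs correlated at 0.959 to 0.997 (median 0.985).

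**Figure D1:**
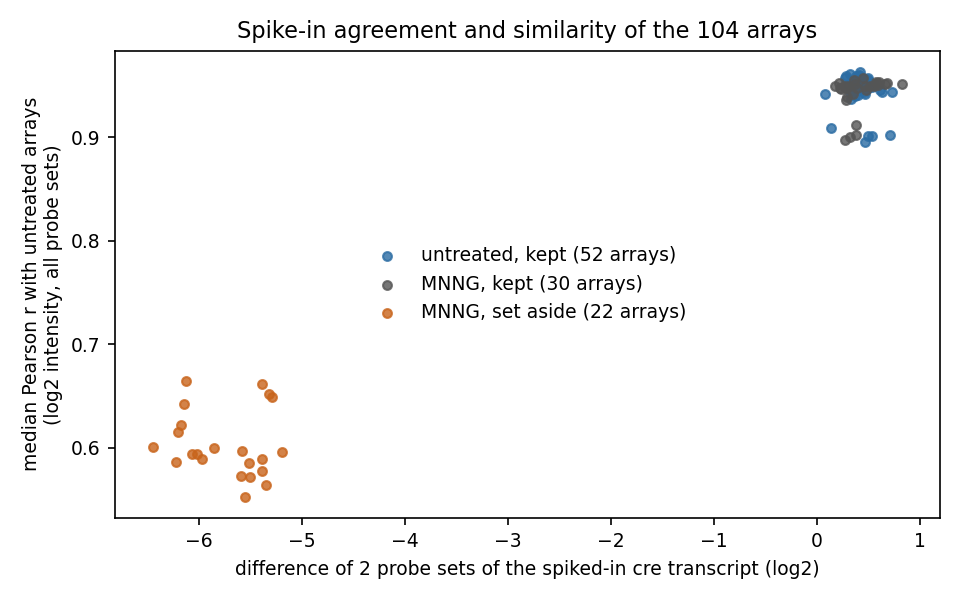
Each point is 1 array, placed by the log2 difference between 2 probe sets of the spiked-in cre transcript (x axis) and by its median Pearson correlation with untreated arrays (y axis), with colours for treatment and use. The 22 MNNG arrays set aside lie at -6.45 to -5.19 and 0.553 to 0.664, and the other 82 at 0.082 to 0.83 and 0.896 to 0.963.

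The panel comparison asked which genes changed with MNNG across lines. In the 19 lines, genes of glycolysis and the hypoxia response fell (as a list, adjusted p = 4.31e-16; adjusted p = 0.254 with an estimated correlation), as did the growth regulator MYC, while several genes that answer DNA damage rose by small amounts. The glycolytic regulator PFKFB4 (-0.88 ± 0.094), the collagen prolyl hydroxylase P4HA1 (-0.86 ± 0.068) and the aldolase ALDOC (-0.78 ± 0.12) fell in 19 of 19 lines, and the pyruvate kinase PKM (-0.70 ± 0.061) fell in 18. MYC, a transcription factor that drives growth, fell in 19 of 19 lines (-0.62 ± 0.043, adjusted p = 8.21e-09). Rises in 19 of 19 lines were seen for MDM2, a ubiquitin ligase induced by DNA damage (0.47 ± 0.088, adjusted p = 0.000153), for the growth-arrest gene GADD45A (0.47 ± 0.074) and for TIGAR (0.48 ± 0.062), a bisphosphatase that slows glycolysis.

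The largest falls included the nuclear matrix protein MATR3 (-1.21 ± 0.15), down in 16 lines, the transcription factor GTF2I (-1.10 ± 0.084), the nuclear noncoding RNA MALAT1 (-0.98 ± 0.11), and NFKB2 (-0.87 ± 0.078), a subunit of the noncanonical NF-kB pathway, the last 3 down in 18 lines each. The others were the actin-binding gene ABLIM1 (-0.85 ± 0.19), ZNF395 (-0.77 ± 0.088), and ARPC4 (-0.77 ± 0.093), a subunit of the complex that branches actin. Among the largest rises were the stress kinase MAP3K12 (0.88 ± 0.14), the histone H4 methyltransferase KMT5A (0.72 ± 0.067), the growth factor FGF9 (0.65 ± 0.15), the interferon-induced chemokine CXCL10 (0.65 ± 0.076), and TNFSF4 (0.64 ± 0.13), which encodes the costimulatory protein OX40 ligand. The others were the antisense transcript PAPLN-AS1 (0.82 ± 0.21), the ribosomal protein paralogue RPL10L (0.59 ± 0.12), the heparan sulfatase SULF2 (0.59 ± 0.13), the prenyltransferase subunit PGGT1B (0.58 ± 0.072), and the divergent transcript GALNT7-DT (0.57 ± 0.20). Each of these 10 rose in 16 or more of the 19 lines, and the call of GALNT7-DT ended when all its probe sets were averaged (0.17).

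With all arrays, limma called 9685 of 13842 genes in the 24 lines (5810 up, 3875 down), of which 873 up and 2329 down changed at least 1.5-fold. From the 82 arrays it called 5892 genes in 19 lines (3978 up, 1914 down), of which only 13 up and 33 down changed at least 1.5-fold. Of 13454 genes tested in both, 4139 were called in both, and 1422 of these moved in opposite directions. The probe set of a gene was chosen anew for each set of arrays, so some genes were represented by different probe sets. The split between rises and falls depended on the scaling of the arrays. For the 82 arrays it was 4100 up and 961 down on values as deposited, and 950 up and 2341 down with each array centred on its median. In the 82 arrays the count was 1188 when the arrays of replicate 1 were left out, which kept only 10 of the 19 lines, and 2097 without the line as a block, and with all arrays it was 5100 without replicate 2. The calls of MDM2 and of CDKN1A, the kinase inhibitor that halts the cell cycle (0.28 ± 0.085, up in 14 and down in 5 lines), ended with median-centring (0.31 and 0.13) and in the 10 lines without replicate 1 (0.52 and 0.35). In those 10 lines the calls of ABLIM1 (-0.80), FGF9 (0.58), PGGT1B (0.34), RPL10L (0.39) and PAPLN-AS1 (0.53) ended too, with their directions kept. With all arrays, GADD45A (-0.17), CDKN1A (-1.74) and RPL10L (-0.56) moved the other way.

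Of 28 gene lists fixed before the data were examined, 7 were called in the panel, 0 of them when the correlation between genes was estimated (3 lists had an unadjusted p below 0.05 there, with limma's camera) rather than preset. The glycolysis and hypoxia list fell (-0.34 on average, adjusted p = 4.31e-16; adjusted p = 0.254 with an estimated correlation). Of its 28 measured genes 0 rose, 22 fell and 6 did not pass, with 0 up and 23 down adjusted over the list alone. The amino acid response list, driven by ATF4, fell (-0.096, adjusted p = 0.000206; 0.326 as the adjusted p with an estimated correlation). Of its 24 genes 1 rose, 11 fell and 12 did not pass, with 1 up and 11 down adjusted over the list alone. Its members included the alanyl-tRNA synthetase AARS1 (-0.35 ± 0.037) and DDIT4 (-0.35 ± 0.052), an inhibitor of mTOR signalling. The cholesterol synthesis list fell (-0.11, adjusted p = 0.00064; adjusted p = 0.376 with an estimated correlation). Of its 17 genes 1 rose, 9 fell and 7 did not pass, with 2 up and 9 down adjusted over the list alone. The transcription factor SREBF2 (-0.37 ± 0.054) and lanosterol synthase LSS (-0.28 ± 0.039) were among them.

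The immediate early list, which holds MYC, fell (-0.087, adjusted p = 0.00064; adjusted p = 0.254 with an estimated correlation). Of its 20 genes 3 rose, 12 fell and 5 did not pass, with 3 up and 13 down adjusted over the list alone. The B-cell identity list fell (-0.10, adjusted p = 0.00675; adjusted p = 0.37 with an estimated correlation). Of its 16 genes 1 rose, 7 fell and 8 did not pass, with 1 up and 7 down adjusted over the list alone. The B-cell receptor kinase BLK (-0.49 ± 0.052) and the surface protein CD37 (-0.36 ± 0.043) fell in 19 of 19 lines. The list of oxidative phosphorylation genes rose by little (0.091, adjusted p = 0.00064; adjusted p = 0.37 with an estimated correlation), but its mean was -0.070 with each array centred on its median. Of its 31 genes 21 rose, 4 fell and 6 did not pass, with 21 up and 4 down adjusted over the list alone, and the respiratory complex I subunits NDUFB8 (0.27 ± 0.023) and NDUFB3 (0.26 ± 0.022) rose in 19 of 19 lines.

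The damage-target list, of arrest, apoptosis and repair genes that are induced after DNA damage, rose (0.15, adjusted p = 0.0268; adjusted p = 0.841 with an estimated correlation). Of its 44 measured genes 27 rose, 5 fell and 12 did not pass, with 29 up and 5 down adjusted over the list alone. Among the falls was ZMAT3, an RNA-binding protein (-0.55 ± 0.069, down in 18 lines), whose call ended when all its probe sets were averaged (-0.11). The call of the list ended with median-centring (0.029) and with the dimmest 50% of genes left out. With all arrays the means of the damage-target list (-0.21) and of oxidative phosphorylation (-0.90, with NDUFB8 at -0.43 and NDUFB3 at -1.66) lay below 0. On values as deposited the median change of all genes was 0.13 in the panel, 0.12 in TK6 and 0.31 in MT1, against 0.037, -0.029 and 0.033 after quantile normalization, and with median-centring it was -0.13 in MT1. Relative to the median of all genes, the panel means were 0.050 for damage targets, -0.45 for glycolysis and hypoxia, -0.18 for the amino acid response and -0.049 for oxidative phosphorylation on values as deposited.

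**Figure D2:**
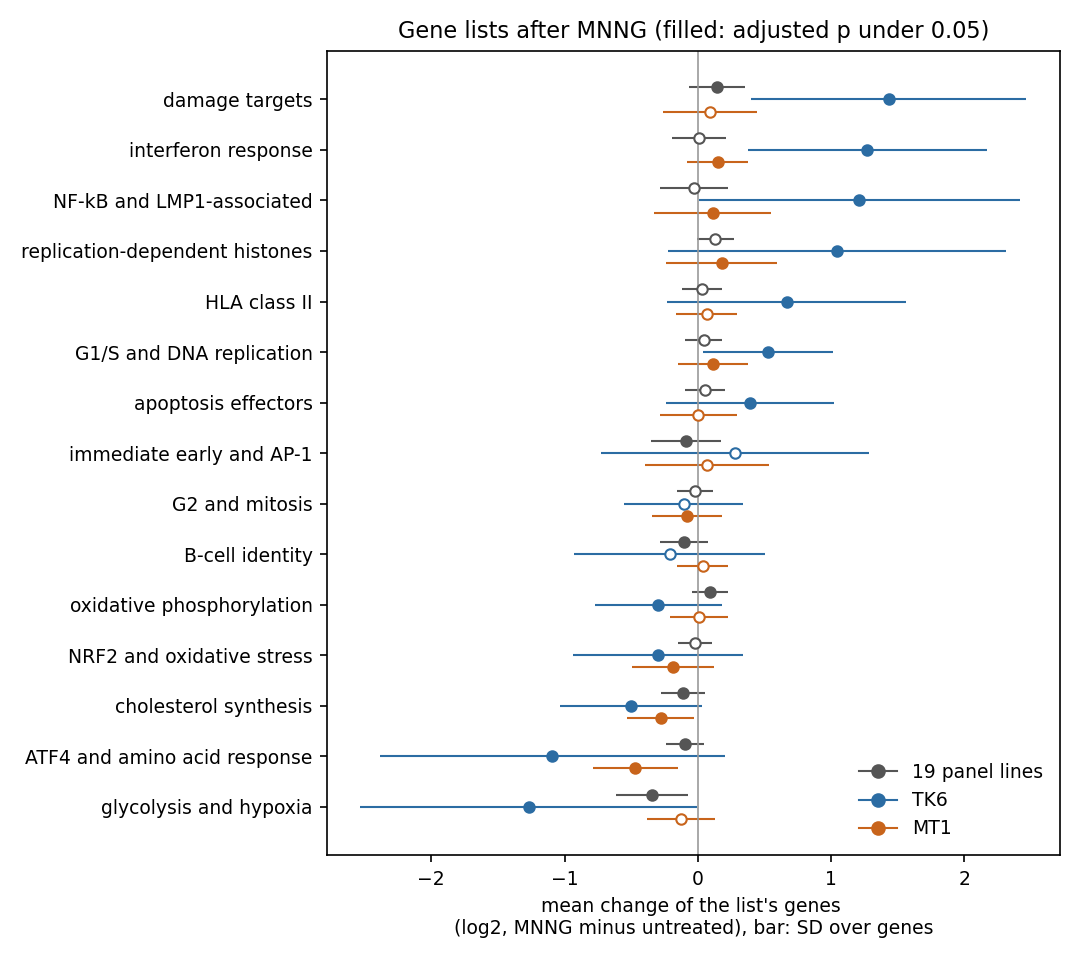
Points give the mean log2 change after MNNG of the genes in 15 lists for 19 panel lines, TK6 and MT1 (82 arrays), bars give the SD over the genes of a list, and filled points were called at the preset correlation, of which 0 in the panel hold with an estimated one. Damage targets had means of 0.15, 1.43 and 0.093, and the small panel rise of oxidative phosphorylation and the small MT1 rises of G1/S and NF-kB genes changed sign with median-centring.

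Lines differed in how they responded to MNNG. The dendritic and B-cell activation marker LAMP3 changed by -0.017 to 1.68 across the 19 lines (SD 0.46, adjusted p = 2.36e-11). CDKN1A changed by -0.23 to 1.29 (SD 0.41, adjusted p = 1.17e-08), MDM2 by 0.022 to 1.93 (adjusted p = 0.000488), and TNFSF4 by -0.093 to 2.51 (SD 0.65). Other genes with the strongest differences were the hypoxia-induced ANKRD37 (-2.10 to -0.037), the ribonuclease RNASET2 (-1.48 to 0.043), the lysosomal fucosidase FUCA1 (-0.15 to 1.69), adenosine deaminase ADA (-0.037 to 1.46) and CD274, the immune checkpoint ligand PD-L1 (-0.32 to 1.10). The histone gene H2BC12 (-0.25 to 0.70) and the vesicle adaptor AP3S1 (-0.62 to 0.015) completed the 10. For MGMT the test of a difference between lines gave an adjusted p of 0.168, and for the mismatch repair gene MSH6 0.0016. The test called 264 of 13842 genes with all arrays and 935 with the 82. With all arrays this F test of limma did not call CDKN1A (adjusted p = 0.484), MDM2 (adjusted p = 0.0519) or MSH6 (adjusted p = 0.496). The 10 genes with the largest F were then all different ones. From all arrays the test called 143, 157 and 163 without line 6, 7 or 11. From the 82 it called 472 without line 4, 54 on values as deposited and 372 with median-centring. Within single lines, the median line had 1.5 called genes with all arrays (0 to 6801 over the lines) and 233 with 82 (4 to 1767). Without 1 array of each group these medians were 0 to 445.5 and 51 to 120.

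Untreated lines differed widely, with ranges between the lowest and the highest line of at least 137-fold for the HLA class II gene HLA-DQA1, at least 79.8-fold for the chitinase-like gene CHI3L2, at least 71.3-fold for the actin-bundling gene PLS3, at least 49.6-fold for the glutathione transferase MGST1 and 38.2-fold for PLAC8. The others with the strongest differences were GPR160 (at least 45.3-fold), P3H2 (at least 41.8-fold), UNC13C (at least 40.7-fold), MACROD2 (at least 39.6-fold) and the glucuronosyltransferase UGT2B17 (at least 25.3-fold). In all of these but PLAC8 the lowest line lay near the bottom of the scale (5.11 to 5.96), so the floor and the pseudocount set these bounds and their sizes cannot be ranked. MGMT ranged at least 10.3-fold, from a log2 level of 5.12, near the bottom of the scale, to 8.48 (SD between duplicates 0.12, adjusted p = 3.29e-20). CDKN1A ranged 4.72-fold, SPATC1L at least 3.90-fold, MDM2 2.50-fold, MSH6 1.91-fold, the alkylpurine glycosylase MPG 1.82-fold (adjusted p = 0.044) and the adenine glycosylase MUTYH 1.58-fold. The test of line called 8833 genes with all arrays, 1119 of them over a range of at least 4-fold, and 8894 (1253) with the 82 arrays. It called 5805 and 5852 genes on values as deposited.

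Among the 19 lines that kept an MNNG array, 4 of the 5 with the least MGMT before treatment had the largest rises of the damage-target list (0.24 to 0.82). The other lay below the mean of all 19 lines. Lines that lost both MNNG arrays are missing here. With all arrays, their untreated MGMT levels included some of the lowest of the panel (5.10 in line 6, 5.78 in line 11) and the highest (8.24 in line 16). The mean change of the list was -0.015 to 0.82 across the 19 lines (mean 0.15, SD 0.20), above 0 in 18 of 19. Across these lines the untreated MGMT level (5.12 to 8.07) correlated with it at Pearson r = -0.866 (permutation p = 6.0e-05, adjusted p = 0.00036 over 6 relations) and Spearman rho = -0.705 (permutation p = 0.00109, adjusted p = 0.00654). All tests of these relations were two-sided. Without the 2 lines farthest from the median MGMT level, both at its low end, r was -0.656 (permutation p = 0.00639) and rho -0.588 over 17 lines. Among the 8 lines that kept both MNNG arrays r was -0.967 (exact permutation p = 0.00459) and rho -0.571 (exact permutation p = 0.151), and among the 11 that kept 1 it was -0.898 (permutation p = 0.0197), with rho -0.845 (permutation p = 0.00216). In the 8 lines the MGMT levels formed 2 clusters, at 5.90 to 6.41 and at 7.54 to 7.75, so their r mainly compares these clusters. Over all 19 lines the levels were uneven, with 14 lines between 7.39 and 8.07 and 5 below. Within those 14 lines, chosen after seeing the levels, r was -0.400 (permutation p = 0.157) and rho -0.367 (permutation p = 0.197), so the relation was not shown within them. It did not pass with all arrays and 24 lines (r = -0.401, permutation p = 0.0521, adjusted p = 0.313; rho = -0.508, permutation p = 0.0128, adjusted p = 0.0767; r = -0.315 without 2 lines, -0.0170 and -0.515 with level and response from different duplicates), nor on values as deposited (r = -0.460, adjusted p = 0.168). SPATC1L, a gene whose function is little known, gave r = -0.628 (permutation p = 0.00801, adjusted p = 0.0240) but rho = -0.274 (permutation p = 0.256, adjusted p = 0.694). Without 2 lines its call, though not its sign, was lost (r = -0.498, permutation p = 0.0432, adjusted p = 0.129; rho = -0.360). MSH6 (r = 0.248, permutation p = 0.303; rho = 0.121, p = 0.622), MPG (r = -0.333, p = 0.169; rho = -0.228, p = 0.347), MUTYH (r = 0.229, p = 0.346; rho = 0.175, p = 0.471) and the mean of the G2 and mitosis list (r = -0.0970, p = 0.693; rho = -0.00351, p = 0.992) did not pass. Their r without 2 lines was 0.314, -0.458, 0.198 and -0.176, and the lowest adjusted p of these 4 was 0.338. The number of relations that passed depended on the scaling, with 4 of the 6 under median-centring and 0 on values as deposited.

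**Figure D3:**
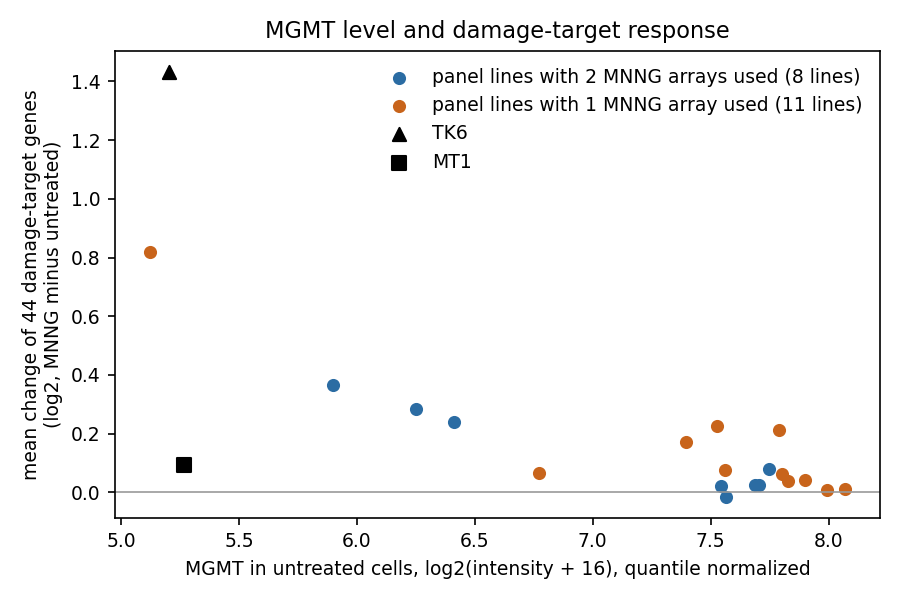
Each circle is 1 of 19 panel lines, by its untreated MGMT level in log2 units (x axis) and the mean log2 change of 44 damage-target genes after MNNG (y axis), coloured by the number of MNNG arrays used; TK6 and MT1 are shown but not part of the correlation (r = -0.866). Among the 14 lines at 7.39 and above r was -0.400, and TK6 (1.43) and MT1 (0.093) lie apart at a like low MGMT level (5.20 and 5.27).

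MGMT itself rose in the panel by 0.33 ± 0.062 with treatment (18 of 19 lines, adjusted p = 0.000179; -0.45 with all arrays). MSH6 changed by -0.21 ± 0.038 (down in 17 lines), SPATC1L by -0.11 ± 0.030 (down in 16) and MUTYH by 0.11 ± 0.028 (up in 15; -0.0072 with median-centring and -0.68 with all arrays), while MPG was not called (-0.045 ± 0.032, adjusted p = 0.273).

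TK6, with 2 arrays in each condition, changed far more in size. CDKN1A rose by 2.95 ± 0.082, from a level of 9.56 to 12.51 (adjusted p = 2.14e-28), and MDM2 by 2.95 ± 0.15 (adjusted p = 5.77e-20). With all arrays limma did not call the rise of CDKN1A (2.99 ± 1.49, adjusted p = 0.478). That of MDM2 was still called (2.98 ± 0.50, adjusted p = 2.49e-05). The largest rise was that of LCE1B, a gene of the cornified envelope of skin (6.81 ± 0.36, from 6.01 to 12.81). Other large rises were those of TNFSF4 (4.87 ± 0.12), the fatty acid hydroxylase CYP4F3 (4.63 ± 0.12), the actin-bundling gene FSCN1 (4.27 ± 0.18), the chemokine CCL4 (3.70 ± 0.13) and the antisense transcript DTNB-AS1 (4.01 ± 0.10). The largest falls were those of PFKFB4 (-4.12 ± 0.13), ALDOC (-3.40 ± 0.16), the neurite growth gene NRN1 (-3.24 ± 0.16), ANKRD37 (-3.18 ± 0.11), the cysteine-forming enzyme CTH (-3.10 ± 0.10) and asparagine synthetase ASNS (-3.07 ± 0.064). Untreated levels were near the bottom of the scale for TNFSF4 (5.34), CYP4F3 (5.56), FSCN1 (5.29), CCL4 (6.05) and LCE1B, and so were treated levels of PFKFB4 (5.52) and NRN1 (6.09), so these changes are lower bounds.

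Of the 28 lists, 12 were called in TK6, 11 of them with an estimated correlation. The damage-target list rose by 1.43 on average (adjusted p = 6.17e-26). Of its 44 genes 37 rose, 0 fell and 7 did not pass, with 37 up and 0 down adjusted over the list alone. The interferon list rose by 1.27 (adjusted p = 2.43e-20). Of its 36 genes 29 rose, 1 fell and 6 did not pass, with 29 up and 1 down adjusted over the list alone. Its members included the guanylate-binding protein GBP1 (3.19 ± 0.14), the chemokine CXCL9 (2.87 ± 0.12) and the apoptosis gene XAF1 (2.48 ± 0.084). The NF-kB list rose by 1.21 (adjusted p = 2.09e-10; 0.0184 as the adjusted p with an estimated correlation). Of its 26 genes 19 rose, 1 fell and 6 did not pass, with 19 up and 1 down adjusted over the list alone. Among them were CCL4, CCL22 (2.89 ± 0.30) and the survival gene BCL2A1 (1.88 ± 0.076). The glycolysis and hypoxia list fell by 1.27 (adjusted p = 2.02e-15). Of its 28 genes 1 rose, 20 fell and 7 did not pass, with 1 up and 21 down adjusted over the list alone, and the mitophagy receptor BNIP3 (-2.97 ± 0.10) fell with PFKFB4 and ALDOC. The amino acid response list fell by 1.09 (adjusted p = 1.83e-11). Of its 24 genes 3 rose, 20 fell and 1 did not pass, with 3 up and 20 down adjusted over the list alone. Among them were ASNS, CTH, stanniocalcin STC2 (-2.69 ± 0.13) and the serine synthesis enzyme PHGDH (-2.64 ± 0.10). The rises of CXCL9, XAF1 and CCL22 started at 5.45, 5.60 and 5.61 and are lower bounds too.

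The G1/S and replication list rose by 0.53 in TK6 (adjusted p = 3.94e-09). Of its 46 genes 37 rose, 3 fell and 6 did not pass, with 38 up and 3 down adjusted over the list alone. The cyclin CCNE2 (1.55 ± 0.16), the DNA methylation factor UHRF1 (1.45 ± 0.098) and the replication clamp PCNA (1.13 ± 0.11) were among them. Replication-dependent histones rose by 1.05 (adjusted p = 5.92e-05). Of the 12 genes 8 rose, 0 fell and 4 did not pass, with 8 up and 0 down adjusted over the list alone, led by H2BC12 (3.58 ± 0.062) and H2AC6 (2.77 ± 0.15), from 6.00. HLA class II genes, which present antigen, rose by 0.67 (adjusted p = 0.000233). Of the 12 genes 8 rose, 1 fell and 3 did not pass, with 8 up and 1 down adjusted over the list alone, and HLA-DMB (2.31 ± 0.074) and HLA-DOB (1.83 ± 0.093), from 5.51, were among the rises. The apoptosis list rose by 0.39 (adjusted p = 0.00255). Of its 24 genes 14 rose, 3 fell and 7 did not pass, with 15 up and 3 down adjusted over the list alone, and the death receptor FAS (1.20 ± 0.11) rose. Cholesterol synthesis fell by 0.50 (adjusted p = 0.00255). Of its 17 genes 2 rose, 10 fell and 5 did not pass, with 2 up and 12 down adjusted over the list alone. The squalene epoxidase SQLE (-1.51 ± 0.17) was among the falls. The oxidative stress list, of NRF2 targets, fell by 0.30 (adjusted p = 0.0225). Of its 20 genes 3 rose, 10 fell and 7 did not pass, with 4 up and 10 down adjusted over the list alone, and the quinone reductase NQO1 (-1.55 ± 0.14) and haem oxygenase HMOX1 (-1.38 ± 0.15) fell. Oxidative phosphorylation fell by 0.29 (adjusted p = 0.00445; adjusted p = 0.0761 with an estimated correlation). Of its 31 genes 2 rose, 15 fell and 14 did not pass, with 2 up and 15 down adjusted over the list alone, and UQCRC1 (-1.14 ± 0.17), a subunit of complex III, fell. MYC fell as well (-2.32 ± 0.12).

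MGMT in TK6 stayed at the bottom of the scale (-0.040 ± 0.17, adjusted p = 0.885, level 5.20 untreated). SPATC1L fell (-1.67 ± 0.23, adjusted p = 1.1e-07), as did MUTYH (-0.37 ± 0.12) and MSH6 (-0.22 ± 0.077), and MPG was not called (-0.48 ± 0.22, adjusted p = 0.0861). With all arrays, 464 of 13842 genes were called in TK6 (323 up, 141 down), and with the 82 arrays 5697 (2996 up, 2701 down), of which 1845 rose and 1527 fell at least 1.5-fold. The TK6 arrays were the same in both, and the spread estimated over all groups was not. With all arrays the split was 672 up and 580 down under median-centring, and the count fell to 216 to 242 when any 1 of the 4 TK6 arrays was left out and to 201 with only the TK6 and MT1 arrays. On the 82 arrays the count was 3623 on values as deposited (2195 up, 1428 down), and with median-centring 2063 rose and 2488 fell, so the majority depended on the scaling.

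MT1 changed in fewer genes, and its damage-target list was not called. After 1 array was set aside, MT1 had 2 untreated arrays and 1 MNNG array, which was assumed to vary like the other groups. CDKN1A was not called (0.087 ± 0.10, adjusted p = 0.776, level 9.04 untreated and 9.13 treated), nor was MDM2 (0.50 ± 0.18, adjusted p = 0.126). ZMAT3 (-0.99 ± 0.26, adjusted p = 0.0256) and the apoptosis inducer PMAIP1 (-0.64 ± 0.16) fell. Large rises were seen for the noncoding RNAs LINC00486 (3.26 ± 0.88) and LINC00944 (2.19 ± 0.35), MAP3K12 (2.04 ± 0.61), the mucin MUC13 (1.67 ± 0.42), the death ligand TNFSF10 (1.51 ± 0.29), which encodes TRAIL, and the growth factor BMP2, which rose 2.83-fold. LINC00486 (5.55), LINC00944 (5.40), TNFSF10 (5.78) and MUC13 (6.05) started near the bottom of the scale. The largest falls were the glycyl-tRNA synthetase GARS1 (-1.22 ± 0.23), the Golgi protein GLG1 (-1.21 ± 0.11), the chromatin remodelling subunit BPTF (-1.20 ± 0.21), the membrane protein TM9SF4 (-1.19 ± 0.23), glutamate dehydrogenase GLUD1 (-1.14 ± 0.30) and the endosomal protein WASHC4 (-1.09 ± 0.22).

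The amino acid response list fell in MT1 as well, by 0.47 (adjusted p = 1.15e-20). Of its 24 genes 0 rose, 11 fell and 13 did not pass, with 0 up and 17 down adjusted over the list alone. Among them were AARS1 (-0.97 ± 0.12) and CTH (-0.87 ± 0.13). Cholesterol synthesis fell by 0.28 (adjusted p = 1.51e-05), although of 17 genes 0 rose, 0 fell and 17 did not pass, with 0 up and 6 down adjusted over the list alone (LSS -0.56 ± 0.17, adjusted p = 0.0574). The oxidative stress list fell by 0.19 (adjusted p = 0.00139). Of its 20 genes 0 rose, 3 fell and 17 did not pass, with 0 up and 4 down adjusted over the list alone, and HMOX1 (-0.95 ± 0.18) fell. The interferon list rose by 0.15 (adjusted p = 0.00833). Of its 36 genes 3 rose, 0 fell and 33 did not pass, with 9 up and 1 down adjusted over the list alone, and the antiviral gene IFIT1 (0.53 ± 0.14) rose, from 5.93. These 4 lists were also called with an estimated correlation, and 4 more were called only with the preset one. Histones rose by 0.18 (adjusted p = 0.0329; adjusted p = 0.109 with an estimated correlation). Of the 12 genes 3 rose, 0 fell and 9 did not pass, with 5 up and 1 down adjusted over the list alone, and H2BC12 (0.68 ± 0.076) rose. The NF-kB list rose by 0.11 (adjusted p = 0.0344; adjusted p = 0.545 with an estimated correlation), with a mean of -0.16 under median-centring. Of its 26 genes 5 rose, 0 fell and 21 did not pass, with 6 up and 1 down adjusted over the list alone, and BCL2A1 (0.75 ± 0.093) and the adhesion receptor CD44 (0.77 ± 0.089) rose. G1/S genes rose by 0.12 (adjusted p = 0.0433; adjusted p = 0.0978 with an estimated correlation), with a mean of -0.19 under median-centring. Of the 46 genes 5 rose, 1 fell and 40 did not pass, with 10 up and 2 down adjusted over the list alone, CCNE2 (0.74 ± 0.19) among the rises. G2 and mitosis genes fell by 0.080 (adjusted p = 0.0433; adjusted p = 0.0737 with an estimated correlation). Of the 40 genes 2 rose, 1 fell and 37 did not pass, with 2 up and 1 down adjusted over the list alone, and the proliferation marker MKI67 (-0.70 ± 0.17) fell. With all arrays the means of the NF-kB (-0.35) and G1/S lists (-0.38) in MT1 lay below 0, as did BCL2A1 (-1.22) and CD44 (-0.81), and PMAIP1 (0.26) and WASHC4 (0.39) lay above 0.

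The damage-target list had a mean of 0.093 in MT1 (adjusted p = 0.244; -0.21 under median-centring). Of its 44 genes 4 rose, 2 fell and 38 did not pass, with 7 up and 5 down adjusted over the list alone. Relative to the median of all genes on values as deposited, its mean was -0.080, and that of the amino acid response list -0.65. MYC fell (-0.94 ± 0.15). MGMT (-0.13 ± 0.20), MSH6 (-0.15 ± 0.095), MUTYH (-0.0097 ± 0.15), MPG (-0.078 ± 0.27) and SPATC1L (-0.77 ± 0.28) were not called, with adjusted p of 0.852, 0.501, 0.989, 0.948 and 0.137. With all arrays 14 genes were called in MT1 (8 up, 6 down), among them SPATC1L (-1.91 ± 0.41, adjusted p = 0.0440 by limma). Leaving out the MNNG array of the 82, so that the one set aside stood alone, gave 2215, leaving out the one set aside gave 0 by limma (74 with an unadjusted p below 0.05), and leaving out either untreated array gave 4 or 1. With the 82 arrays 493 were called (326 up, 167 down; 123 and 62 at least 1.5-fold), 92 up and 7 down on values as deposited and 15 up and 52 down under median-centring, and 212 or 326 in all without either untreated array. With only the TK6 and MT1 arrays limma called 0 genes, 1623 having an unadjusted p below 0.05, so every MT1 call rests on the spread of the other lines.

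The responses of TK6 and MT1 differed in the damage-target genes and in many others, by a test of the difference itself. The rise of CDKN1A was larger in TK6 by 2.86 ± 0.13 (adjusted p = 1.84e-20) and that of MDM2 by 2.44 ± 0.23 (adjusted p = 6.1e-11). With all arrays limma called neither difference, at 4.60 ± 2.11 for CDKN1A (adjusted p = 0.503) and 2.04 ± 0.70 for MDM2 (adjusted p = 0.219). Among the largest positive differences were those of LCE1B (6.77 ± 0.57), FSCN1 (4.30 ± 0.28), CYP4F3 (4.20 ± 0.19), TNFSF4 (4.07 ± 0.19) and the galectin LGALS9 (4.01 ± 0.43). The largest negative differences were those of PFKFB4 (-3.82 ± 0.20), NRN1 (-3.36 ± 0.25), LINC00486 (-3.35 ± 1.14), ANKRD37 (-3.18 ± 0.18), BNIP3 (-3.10 ± 0.17) and ALDOC (-3.08 ± 0.25). For LCE1B, FSCN1, CYP4F3, TNFSF4, LGALS9, PFKFB4, NRN1 and LINC00486 some of the 4 levels lay near the bottom of the scale, so these differences are not exact. NRN1 lay there in MT1 both untreated (5.27) and treated (5.38), so a fall in MT1 could not have been seen. The responses of MGMT (0.090 ± 0.26, adjusted p = 0.878) and SPATC1L (-0.89 ± 0.37, adjusted p = 0.0734) were not shown to differ.

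Of the 28 lists, 10 differed between the responses, 9 of them with an estimated correlation. The difference was 1.34 for damage targets (adjusted p = 3.34e-32; 37 of 44 genes higher, 0 lower, and 37 up and 1 down adjusted over the list alone) and 1.12 for interferon genes (adjusted p = 2.5e-22; 26 of 36 higher, 1 lower, and 26 up and 2 down adjusted over the list alone), with GBP1 (2.62 ± 0.22) and XAF1 (2.40 ± 0.13). It was 1.10 for the NF-kB list (adjusted p = 4.42e-10; 16 of 26 higher, 1 lower, and 19 up and 1 down adjusted over the list alone), with CCL4 (2.98 ± 0.21), and 0.87 for histones (adjusted p = 3.71e-05; 5 of 12 higher, 0 lower, and 6 up and 0 down adjusted over the list alone), with H2BC12 (2.91 ± 0.098). It was 0.60 for HLA class II (adjusted p = 6.79e-05; 6 of 12 higher, 1 lower, and 7 up and 1 down adjusted over the list alone), with HLA-DMB (1.85 ± 0.12), 0.41 for G1/S genes (adjusted p = 8.61e-07; 21 of 46 higher, 2 lower, and 24 up and 2 down adjusted over the list alone), with the ribonucleotide reductase subunit RRM1 (1.01 ± 0.15), and 0.39 for apoptosis genes (adjusted p = 0.000699; 9 of 24 higher, 1 lower, and 9 up and 1 down adjusted over the list alone), with FAS (1.33 ± 0.18). It was -1.14 for glycolysis and hypoxia (adjusted p = 3.94e-17; 1 of 28 higher, 19 lower, and 1 up and 19 down adjusted over the list alone) and -0.62 for the amino acid response (adjusted p = 2.31e-06; 4 of 24 higher, 13 lower, and 4 up and 15 down adjusted over the list alone), with ASNS (-2.29 ± 0.10). For oxidative phosphorylation it was -0.31 (adjusted p = 0.0044; adjusted p = 0.0837 with an estimated correlation), with 1 of 31 genes higher, 12 lower, and 2 up and 14 down adjusted over the list alone, including the complex I subunit NDUFA9 (-0.74 ± 0.12), but with all arrays the list (0.76) and NDUFA9 (1.22) lay above 0. Since XAF1 (5.60 in untreated TK6) and CCL4 (5.60 in untreated MT1) lay near the bottom of the scale, their differences are not exact either. Untreated levels of some glycolysis and hypoxia genes differed as well. P4HA1 was at 10.90 in untreated TK6 and 9.04 in untreated MT1, and KDM3A at 10.42 and 8.41. After MNNG the levels were alike, at 8.40 and 8.47 for P4HA1 and 8.08 and 8.09 for KDM3A. In these genes the larger fall in TK6 started from a higher untreated level. Whether untreated levels account for the difference of the list was not tested. Across the 5697 genes called in TK6 the TK6 and MT1 responses correlated at r = 0.402 across genes, which are not independent replicates.

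The difference between the responses was called for 126 genes with all arrays (86 up, 40 down) and for 3415 with the 82 arrays (1682 up, 1733 down; 1152 and 530 with median-centring). With all arrays it was called for 658 genes without the MT1 MNNG array of the 82 and for 68 to 80 without any 1 of the other 7 TK6 and MT1 arrays. From the 82 it was called for 1294 genes on values as deposited and 1915 with only the TK6 and MT1 arrays.

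**Figure D4:**
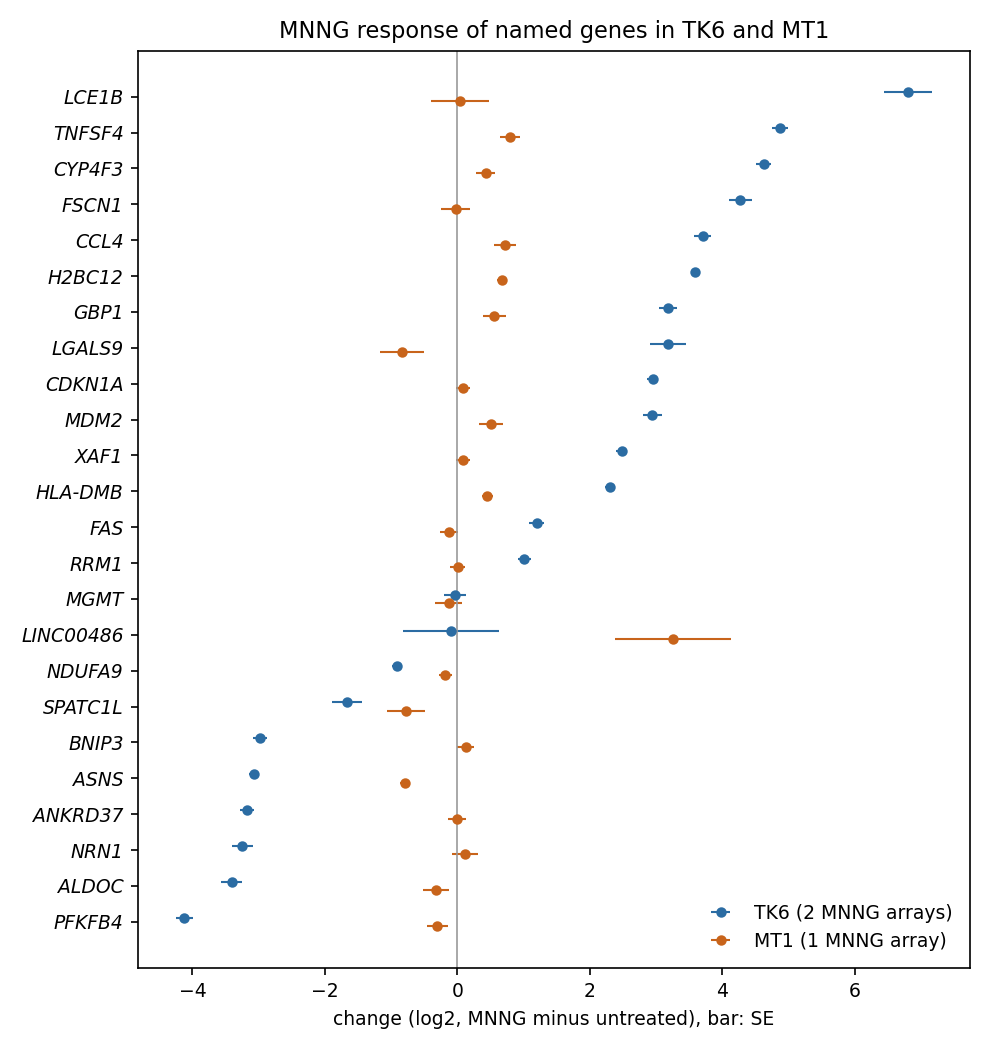
Points give the log2 change after MNNG (x axis) of 24 named genes in TK6 and MT1, and bars give the standard error from the model. CDKN1A rose by 2.95 in TK6 and changed by 0.09 in MT1, and for MGMT and SPATC1L the responses were not shown to differ.

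Untreated MT1 and TK6 also differed, which bears on the background of the comparison above. MT1 had more of the haemoglobin gene HBD (4.78 ± 0.10), the kinase subunit PRKACB (4.66 ± 0.11), CXCL10 (4.50 ± 0.11), the annexin ANXA1 (3.87 ± 0.22), the noncoding RNA LINC02097 (3.44 ± 0.97) and PTAFR (3.32 ± 0.12), the receptor for platelet-activating factor. MT1 had less of SIRPG (-4.84 ± 0.12), of MS4A1 (-4.80 ± 0.060), which encodes the B-cell antigen CD20, of the lysosomal protein LAPTM5 (-4.46 ± 0.093), and of MAGED1 (-4.32 ± 0.11), MYMX (-4.17 ± 0.39) and NRN1 (-4.07 ± 0.16). The lower levels of CXCL10 (5.82), LINC02097 (5.38), SIRPG (5.69), MAGED1 (5.92) and NRN1 (5.27) were near the bottom of the scale, so these are lower bounds. CDKN1A (-0.52 ± 0.082) and MUTYH (-0.84 ± 0.12) were lower in MT1. MGMT (0.064 ± 0.17, adjusted p = 0.871), MSH6 (-0.12 ± 0.077, adjusted p = 0.29), MPG (-0.42 ± 0.22), SPATC1L (0.36 ± 0.23) and MDM2 (-0.0018 ± 0.15) were not called. With all arrays 178 genes were called (33 higher and 145 lower in MT1), and with the 82 arrays 3494 (1880 higher, 1614 lower). With all arrays the split was 125 higher and 230 lower on values as deposited and 151 and 334 with median-centring, and the count was 86 to 95 without any 1 of the 4 arrays. With the 82 arrays the count was 1591 on values as deposited (752 higher, 839 lower) and 2057 with median-centring (924 higher, 1133 lower), so the majority depended on the scaling.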

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

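The tests on the 22 arrays that stand apart, and all values from the 82 other arrays, were chosen only after the result was seen.

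MNNG responses that differed between TK6 and MT1, by a test of the difference, involved 3415 genes. The mean differences of the 10 lists (TK6 minus MT1) were 1.34 for damage targets, -1.14 for glycolysis and hypoxia, 1.12 for interferon genes, 1.10 for the NF-kB list, 0.87 for histones, -0.62 for the amino acid response, 0.60 for HLA class II, 0.41 for G1/S genes, 0.39 for apoptosis genes and -0.31 for oxidative phosphorylation. The last was not called with an estimated correlation, and with all arrays it lay above 0 (0.76). Between panel lines, responses differed in 935 genes by the F test. Outside the genes analysed, an unnamed probe set had a mean log2 value of 15.7 (SD 0.19) in the 22 arrays and 7.21 (SD 0.77) in the other 82.

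Several technical explanations were weighed for the 22 arrays, against an effect of MNNG on the cells. A change of the cells' RNA would leave spiked-in transcripts as they were, but in 22 of the 22 arrays with a low correlation with untreated arrays, and in 0 others, the cre probe sets parted. Degraded cell RNA would spare the spiked-in bioD transcript as well, but its pair of probe sets differed by -4.95 (SD 0.32) in the 22 arrays against 1.22 (SD 0.13) in the others, a shift of -6.17. A candidate explanation is that these arrays were summarised differently before deposit: among 504 genes with several bright probe sets, a median of 52.6% (49.4% to 56.3%) had 1 probe set kept and another lost, against at most 0.397% in other MNNG arrays. In all 22, 632 of 3315 bright probe sets were lost, 770 were lost in none, and 83 of 36799 dim ones were raised, but a fault of the arrays themselves would give the same values and stays open.

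For the count of genes in the panel, 1 of 100 swaps of treated and untreated within lines, the real one, gave as many. That is the smallest share that 100 swaps can show. Such swaps cannot tell an effect of MNNG from a technical shift shared by the treated arrays. With 24 lines the real count was 9685 and the highest other 7884, which points to a structure of the samples. With 19 lines the real count was 5892 and the highest other 0. The high counts of other swaps thus went with the arrays set aside and the 5 lines lost with them. The count of 9685 therefore does not measure a response to MNNG alone.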

How the results depend on the processing

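Setting the 22 arrays aside, every alternative on the 82 arrays, the pseudocount of 0 and the background covariate were chosen only after the result was seen. Setting the 22 aside changed the counts more than any other choice for TK6, TK6 minus MT1 and untreated MT1 minus TK6. Dim probe sets near the floor limit what can be seen, background (log2 of the 25th percentile) being 4.59 (SD 0.46) in the untreated and 4.83 (SD 0.39) in the MNNG arrays of the 82. The cause of each change below was not tested, except that fewer arrays, fewer genes or a smaller residual spread come with the alternative itself. No replicate block could be fitted for MT1 minus TK6 untreated. In a replicate block, replicate numbers were taken as pairs, but they did not pair the arrays: in 9 lines checked, the correlation of their residuals was -0.62 to 0.14 (median -0.045), over 0.1 in 2.

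With all arrays, the count for MT1 (14) was 4 and 33 with pseudocounts 1 and 64, 25 as deposited, 131 median-centred, 43 with no filter, 7 with a 50% filter, 29 with the mean of probe sets, 9 without trend, 1 with a replicate block, 0 with only the TK6 and MT1 arrays (limma; 651 with an unadjusted p below 0.05), 0 to 2215 without 1 array and 493 without the 22. For TK6 (464) it was 959 as deposited, 1252 median-centred, 809 with the mean of probe sets, 201 with only the TK6 and MT1 arrays, 216 to 242 without 1 array and 5697 without the 22. For TK6 minus MT1 (126) these were 274, 481, 267, 17, 68 to 658 and 3415, with 193 under no filter and 73 under the 50% filter. For untreated MT1 minus TK6 (178) they were 355, 485, 302, 108, 86 to 95 and 3494. Single lines (1.5) gave 5.5 with pseudocount 64, 5 as deposited, 17 median-centred, 4 with no filter, 3.5 with the mean of probe sets, 0.5 with a replicate block, 0 to 445.5 without 1 array and 233 without the 22. Untreated lines gave 5805 as deposited. Response differences between lines (264) gave 166 with the 50% filter, 91 with a replicate block, 143 to 345 without 1 line and 935 without the 22. The panel (9685) gave 3504 with array weights, 5100 to 9737 without 1 line or replicate and 5892 without the 22. Called lists in the panel (10) were 4 with the 50% filter, 6 to 7 without a replicate, 0 with an estimated correlation (camera; 3 with an unadjusted p below 0.05) and 19 with fry, and in MT1 (10) 5, 4 with an estimated correlation and 4 with fry. Relations past the threshold (0) were 1 with the median of the list and 2 without the 22, where r of MGMT (-0.401) was -0.571 and -0.866. In the other settings r of MGMT was -0.515 to -0.0170, weakest with the level from replicate 2 and the response from replicate 1, and -0.149 as deposited.

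With the 82 arrays, response differences between lines (935) gave 54 as deposited, 372 median-centred, 111 with a replicate block and 472 to 1076 without 1 line, and untreated lines gave 5852 as deposited. Single lines (233) gave 14 as deposited, 22 median-centred, 55 with a replicate block and 51 to 120 without 1 array. TK6 gave 3623 as deposited. MT1 (493) gave 99 as deposited, 67 median-centred, 113 with a replicate block, 0 with only the TK6 and MT1 arrays (limma; 1623 with an unadjusted p below 0.05) and 212 to 326 without 1 array. As deposited, median-centred and with only the TK6 and MT1 arrays, TK6 minus MT1 gave 1294, 1682 and 1915, and untreated MT1 minus TK6 gave 1591, 2057 and 2225. The panel (5892) gave 3291 median-centred, 2097 without line block and 1188 to 6262 without 1 line or replicate. Relations past the threshold (2) were 0 as deposited, where r of MGMT was -0.460, 4 median-centred, 1 in each direction of split duplicates and 1 without 2 lines. With quantile normalization, r of MGMT was -0.400 in only the 14 lines with a level above 7. Called lists were, with fry, 18 in the panel, 26 in TK6, 15 in MT1 and 22 for TK6 minus MT1, with an estimated correlation 0 in the panel and 4 in MT1, and in MT1 5 with the 50% filter and 5 with the mean of probe sets.

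Directions reversed with all arrays, in the panel, for GADD45A (-0.17), CDKN1A (-1.74), RPL10L (-0.56), NDUFB8 (-0.43), NDUFB3 (-1.66), MGMT (-0.45), MUTYH (-0.68), TNFRSF17 (-1.26), RAD51C (-0.23), HSPE1 (-0.32), SDF2L1 (-0.95), MANF (-0.95) and the lists of ribosomal proteins (-1.33), G1/S genes (-0.45), oxidative phosphorylation (-0.90), damage targets (-0.21), ribosome biogenesis (-0.61) and the unfolded protein response (-0.89). They reversed in MT1 for WASHC4 (0.39), CD44 (-0.81), BCL2A1 (-1.22), PMAIP1 (0.26) and the lists of ribosomal proteins (-1.33), G1/S genes (-0.38), heat shock (-1.16), NF-kB (-0.35), oxidative phosphorylation (-1.10), ribosome biogenesis (-0.62) and the unfolded protein response (-0.80), and in TK6 minus MT1 for NDUFA9 (1.22) and oxidative phosphorylation (0.76). Among genes and lists called in either setting, median-centring reversed MUTYH (-0.0072), ribosomal proteins (-0.19) and oxidative phosphorylation (-0.070) in the panel, and ribosomal proteins (-0.49), G1/S genes (-0.19), NF-kB (-0.16) and oxidative phosphorylation (-0.41) in MT1, while list means not called in either setting also changed sign, such as damage targets in MT1 (-0.21). Relative to the median of all genes, which moved too, oxidative phosphorylation in the panel (0.054 to -0.049) and G1/S (0.084 to -0.062) and NF-kB genes (0.079 to -0.025) in MT1 changed sign. MUTYH stayed above that median, and ribosomal proteins (-0.014 to -0.17 in the panel, -0.021 to -0.35 in MT1) and oxidative phosphorylation in MT1 (-0.022 to -0.28) stayed below it. Values as deposited reversed ribosomal proteins (-0.036) and the oxidative stress list (0.0053) in the panel and ribosomal proteins (-0.042) and glycolysis and hypoxia (0.018) in MT1. None of these 4 reversed relative to the median of all genes, where they were -0.17, -0.13, -0.35 and -0.29, against -0.014, -0.057, -0.021 and -0.16 with quantile normalization. Leaving out replicate 2 reversed SPATC1L in the panel (-0.12 to 0.023 over all lines and replicates left out). With all arrays, genes named for the panel kept direction and side of the threshold in 29 cases, lost the call in 6 and reversed in 12. For TK6 these were 26 and 22, and for MT1 7 and 20, with 4 reversed. For TK6 minus MT1 they were 11 and 12, with 1 reversed, and for untreated MT1 minus TK6 15 and 4. In the panel and in MT1, 1 gene each gained the call. Across the other settings of the 82 arrays, genes named for the panel kept direction and side of the threshold in 645 values and lost the call in 25, those for TK6 in 518 and 6, those for MT1 in 278 and 68, those for TK6 minus MT1 in 258 and 2, and those for untreated MT1 minus TK6 in 186 and 1.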

Other observations

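Values here come from the 82 arrays unless all arrays are named, and the choice of these arrays, the background term, and the comparisons among lines by their number of MNNG arrays or by MGMT level were made only after the result was seen. For the tests of array background, shared arrays, lines far from the median MGMT level and the link between the 2 lists on these arrays, what each would show was written down before its own value was computed.

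Some genes of plasma-cell differentiation moved although their list was not called. PRDM1, the transcription factor that drives B cells toward plasma cells, rose in the panel (0.57 ± 0.060, 19 of 19 lines, adjusted p = 1.2e-07) and in TK6 (2.25 ± 0.10), and TNFRSF17, the survival receptor of plasma cells, rose in both (0.35 ± 0.038 and 2.30 ± 0.13). In TK6 the antibody-assembly chaperone MZB1 (-2.72 ± 0.14) fell, and the list went both ways (mean 0.24, 5 up and 3 down of 14, adjusted p = 0.252; in the panel 0.12, 9 up and 1 down of 14, adjusted p = 0.167). Genes of other blood cells rose in TK6 too, the killer-cell pore protein PRF1 (2.28 ± 0.14) and the myeloid integrin ITGAM (2.27 ± 0.16), in lists that were not called (T and NK 0.031, 1 up and 2 down of 11, adjusted p = 0.772; myeloid 0.28, 1 up and 0 down of 7, adjusted p = 0.433). PRDM1, TNFRSF17, PRF1 and ITGAM started near the bottom of the scale in TK6 (5.83, 5.91, 5.58 and 5.47), so these rises are lower bounds.

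Among repair genes, RAD51C, which acts in homologous recombination, rose in 19 of 19 panel lines (0.45 ± 0.040, adjusted p = 2.25e-08) and in TK6 (1.98 ± 0.11), where PALB2 (1.59 ± 0.12), which joins the breast cancer proteins in that pathway, and the nucleotide excision sensor XPC (2.17 ± 0.12) also rose. PARP1, which binds strand breaks, fell in 19 of 19 lines (-0.28 ± 0.024). The TK6 lists of homologous recombination (0.29, 9 up and 2 down of 26, adjusted p = 0.1), nucleotide excision (0.054, 7 up and 8 down of 20, adjusted p = 0.822) and mismatch repair (0.23, 9 up and 3 down of 18, adjusted p = 0.108) were not called. In the panel, the endoplasmic reticulum proteins SDF2L1 (0.49 ± 0.078) and MANF (0.42 ± 0.057) rose in 18 lines each while the disulfide isomerase PDIA4 (-0.50 ± 0.075) fell in 16, and the mitochondrial chaperone HSPE1 (0.36 ± 0.048) rose in 19. With all arrays TNFRSF17, RAD51C, SDF2L1, MANF and HSPE1 moved the other way in the panel (-1.26, -0.23, -0.95, -0.95 and -0.32).

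The panel lists not named so far were not called. For repair they were base excision and direct reversal (0.091, 15 up and 2 down of 24, adjusted p = 0.132), homologous recombination (0.057, 9 up and 2 down of 26, adjusted p = 0.568), nucleotide excision (0.043, 8 up and 5 down of 20, adjusted p = 0.84) and mismatch repair (0.0092, 8 up and 6 down of 18, adjusted p = 0.716). For the cell cycle they were damage checkpoint (0.063, 9 up and 1 down of 21, adjusted p = 0.383), G1/S (0.047, 18 up and 8 down of 46, adjusted p = 0.626), G2 and mitosis (-0.021, 8 up and 10 down of 40, adjusted p = 0.11) and histones (0.13, 8 up and 1 down of 12, adjusted p = 0.132). For stress they were heat shock (0.10, 6 up and 1 down of 14, adjusted p = 0.432), the unfolded protein response (0.078, 9 up and 5 down of 21, adjusted p = 0.383), oxidative stress (-0.020, 5 up and 5 down of 20, adjusted p = 0.403) and apoptosis (0.053, 9 up and 3 down of 24, adjusted p = 0.626). For immunity they were interferon (0.0091, 12 up and 7 down of 36, adjusted p = 0.626), NF-kB (-0.028, 5 up and 5 down of 26, adjusted p = 0.383) and HLA class II (0.032, 5 up and 2 down of 12, adjusted p = 0.778). For translation they were ribosomal proteins (0.023, 10 up and 2 down of 30, adjusted p = 0.432) and ribosome biogenesis (0.026, 8 up and 3 down of 23, adjusted p = 0.936). For other cell types they were T and NK (0.018, 1 up and 1 down of 11, adjusted p = 0.704), myeloid (0.081, 2 up and 0 down of 7, adjusted p = 0.887) and fibroblast and epithelial markers (0.018, 1 up and 1 down of 10, adjusted p = 0.626). With each array centred on its median, these list means lay below 0 except those of histones (0.064) and myeloid markers (0.045). The test pointed down while the mean lay above 0 for interferon, mismatch repair, ribosome biogenesis, T and NK, myeloid, and fibroblast and epithelial markers, and the median was of the other sign for interferon (-0.0046), T and NK (-0.00037) and NF-kB genes (0.019). Across the 5697 genes called in TK6, the responses of single panel lines correlated with that of TK6 at r = 0.024 to 0.66 (median 0.234, over 0.3 in 6 lines), across genes, which are not independent replicates.

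For the relation of MGMT with the damage-target response, the tests argue against shared arrays, and array background as far as it was measured, as the whole cause. They do not argue against dependence on the lines with the least MGMT. The background measure, the 25th percentile, lay at the floor of 16 in several untreated arrays, so it could not follow a background below that. Its change correlated with the untreated MGMT level at r = 0.531. With each line's change in array background taken out, r was -0.831, and with level and response from different duplicates it was -0.758 (permutation p = 0.00134, 17 lines) and -0.922 (permutation p = 3e-05, 10 lines), against -0.0170 and -0.515 with all arrays. Without the 2 lines farthest from the median MGMT level, both at its low end, r was -0.656, and among the 14 lines above the lowest 5 it was -0.400. A hypothesis that stays is that lines with more MGMT may remove the methylated base before it is signalled, but the scaling remains open since the call was lost on values as deposited (-0.460). MT1, which lacks MGMT and in which a rise of the list was not shown, lacks mismatch repair too, and no protein or killing data were used here.

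The glycolysis and hypoxia list fell in 19 of 19 lines (-0.116 to -0.636, mean -0.343, SD 0.179). The data argue against array background, as far as it was measured, as the source of this fall. The mean adjusted for background was -0.363 (95% interval -0.459 to -0.266), but the background measure lay at the floor in several untreated arrays. The hypothesis that the fall is part of the same response as the damage targets predicted a negative correlation, and r over 19 lines was -0.693 (permutation p = 0.00012; rho = -0.712, permutation p = 0.00107; r = -0.686 without 2 lines). Both changes share the same arrays, so the fall may also follow from dose, density or oxygen in the cultures, which are not given in the sources used here. No test separated these.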
